A study of Mus musculus with 15 samples.

How the data were processed

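Native ChIP-seq of H2A.X was carried out by the submitters on mouse embryonic stem cell lines, with inputs and an IgG control. Reads were aligned with Bowtie2 version 2.0.6 to the mouse genome build mm9, per the submitters' processing notes. The domain caller, its settings, the control of each list and any pooling of samples are not given in the sources used here. Each deposited list belongs to 1 H2A.X sample and names domains decreased against a control, per the names the authors gave the lists. A list gives a chromosome, a start, an end, a state that is the same for every domain, a value in column 5 and a score. The authors' score never exceeded the number of bins in a domain and was used only to rank domains within a list and to weight their length. The value in column 5, a score of undefined meaning that the authors deposited, was used only for its sign. The state names a sample as enriched while the list is named as decreased; the direction is taken from the name of the list. All starts and lengths were multiples of 1300 bp, neighbouring domains did not overlap, and all domains were on the 19 autosomes. Coordinates are 1-based.

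The build was checked against the gene table at hand, which is of GRCm38.p6: 21 domains on chromosome 1 ended beyond its last gene end at 195291439, the last at 197194400. Its coordinates were therefore not used, no gene was assigned, and the planned test of 32 gene lists was not run. The planned comparison of the X chromosome with autosomes was not run because the lists hold no domain on the X chromosome. The lines are male and female per the growth protocol. The sex of each line was not among the labels used here, so sex was not taken into account.

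Samples were grouped by the labelled culturing condition, and Serum/LIF samples were further divided by the S or XS of their titles, whose meaning is not given. This division was made from the titles, but the sizes of the lists in bytes were visible when it was made. The H2A.X sample of line 34 in its S culture, the 3 inputs and the IgG sample, 5 samples in all, have no list among those analysed here. The number in a title was taken as the number of the cell line and pairs samples across cultures. As a check of this pairing, the list of 2i/LIF line 34 had a Jaccard index of 0.577 with the 2i/LIF then Serum/LIF list of its own number and 0.583 with that of line 37. For the 2i/LIF list of line 37 the values were 0.543 and 0.531, so lists of the same number hardly differed in overlap from lists of different number.

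Each list was turned into covered and uncovered bins of 1300 bp between the first and last bin that any list covers on each chromosome, 2412.2 Mb in all. Number of domains and covered length were compared between groups by two-sided exact permutation tests of the difference of means, with Benjamini-Hochberg adjustment over 12 comparisons. Overlap within and between the 4 groups, S and XS apart, was tested by exact permutation over all relabellings. Chance overlap of lists, shared length and retention came from 1000 circular shifts of a list along each chromosome, for which 0.001 is the smallest p possible; regions count as touched from 1 bin on. The regions named were fixed before the data were examined as the 10 longest merged regions touched by all 2i/LIF lists and no S list and the 5 longest touched by every list of each other group. Because the widest lists join merged regions over megabases, unbroken stretches of bins were ranked as well, after seeing the data.

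Alternatives fixed before the data were examined were a minimum domain length of 10 kb, the higher-scoring 50% of each list, joining of domains closer than 10 kb, a log10 scale, leaving out each replicate, the line as a block, an overlap of at least 50%, and lists reduced at random to the same number of domains. Alternatives added later were the omission of chromosomes 6, 8 and 13, the omission of the S lists, S and XS lists as 1 labelled culture in the test of overlap, a correlation of lists over bins, and the length in place of the number of shared regions. The circular-shift test was tested on simulated lists of 2600 domains with 100 shifts each. Of 40 unrelated pairs, 1 had a p under 0.05 and the mean ratio of observed to expected overlap was 1.01. All 20 pairs with planted overlap were recovered, with a lowest ratio of 2.03. The simulated domains were placed at random over the span, whereas the deposited lists have stretches in common that no list covers. The simulation therefore does not show how often unrelated lists with such stretches would exceed the shifts. The lists give no read counts, so the depth of each sample is unknown and no counting interval was computed. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.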

Results

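H2A.X, a variant of histone H2A known for its phosphorylation at DNA double-strand breaks, was mapped by native ChIP-seq in mouse embryonic stem cells. Native ChIP immunoprecipitates nucleosomes from nuclease-digested chromatin that was not crosslinked. The cells were grown in Serum/LIF on feeder cells, in serum-free 2i/LIF with the Mek inhibitor PD0325901 at 1 µM and the Gsk3 inhibitor CHIR99021 at 3 µM, or first in 2i/LIF and then in Serum/LIF. The question named for the series is whether the deposition pattern of H2A.X differs between these cultures. The series held 15 samples, of which 11 were H2A.X immunoprecipitates, 3 were inputs and 1 was an IgG control. Lists of decreased domains, by their names regions with less H2A.X than a control, were analysed for 10 of the H2A.X samples. There were 3 lists from 2i/LIF (lines 34, 35 and 37), 2 from 2i/LIF then Serum/LIF (lines 34 and 37), 3 from Serum/LIF cultures titled XS (lines 30, 31 and 32) and 2 from Serum/LIF cultures titled S (lines 35 and 37). The lists give no read counts, so the sequencing depth behind each is unknown. Whether the samples of a group come from separate cultures is not stated, so the p-values of comparisons between groups measure only the spread between these samples, which may be technical. The p-values from circular shifts concern the positions of domains along chromosomes and hold no spread between samples. Shifted domains also fall where no list has a domain, 8.36% of the span, so lists that share only these gaps could exceed the shifts.

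The 2i/LIF lists covered large parts of every autosome, whereas the Serum/LIF S lists covered almost nothing. In 2i/LIF the lists held 2977 ± 327 domains (SD, n = 3) over 1267 ± 550 Mb, which was 52.5% ± 22.8 of the autosomal span of 2412.2 Mb. The S lists held 78 ± 73.5 domains (SD, n = 2) over 5.05 ± 5.85 Mb, or 0.210% ± 0.242 of the span. Line 35 had 3184 domains over 1886 Mb in 2i/LIF and 26 domains over 0.920 Mb in its S culture. Line 37 had 3147 domains over 1080 Mb in 2i/LIF and 130 domains over 9.19 Mb in its S culture. Every 2i/LIF list exceeded both S lists, and the difference of 2899 domains and 1262 Mb had an exact permutation p of 0.2, two-sided, which is the smallest that 3 lists against 2 allow. The S domains were also of another kind by 2 measures: they overlapped the domains of the other 8 lists less than chance in all 16 pairs, and a deposited value of undefined meaning was above 0 in all 156 of them but in at most 16.8% of the domains of any other list. The comparison of sizes takes no account of this difference in kind.

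**Figure D1:**
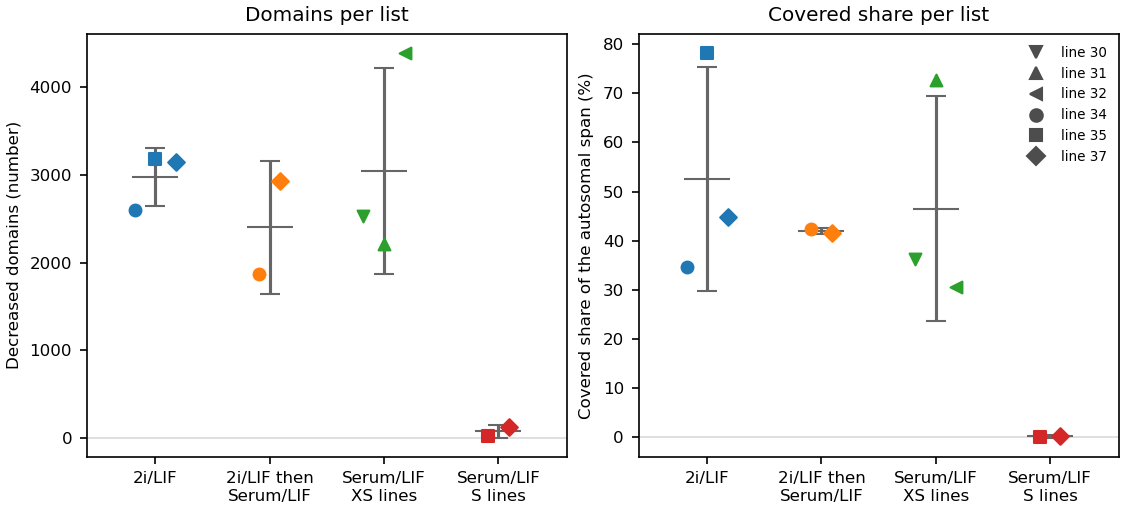
Number of decreased domains (left) and share of the autosomal span they cover in percent (right) for each of the 10 lists, grouped by culture; each symbol is 1 list with its shape giving the line, and the grey bars give the mean ± SD. Both S lists lie near 0, at 26 and 130 domains, while the lists of 2i/LIF line 35 and XS line 31 stand at 78.2% and 72.8% coverage.

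After the move from 2i/LIF to Serum/LIF the lists remained wide. They held 2402.5 ± 756 domains (SD, n = 2) over 1012 ± 15.1 Mb. Line 34 held 1868 domains over 1023 Mb after the move against 2600 over 834 Mb in 2i/LIF, and line 37 held 2937 over 1001 Mb against 3147 over 1080 Mb. Compared with the 2i/LIF lists, the difference was -574.5 domains (exact permutation p = 0.4, two-sided) and -255 Mb (exact permutation p = 0.8), both within the spread, with 0.2 the smallest p possible. The difference in number was -40 without the list of line 34 after the move and -1109 without that of line 37. Both lines had fewer domains after the move than in 2i/LIF, with a mean paired difference of -471. The direction of the length difference rested on line 35, which has no list after the move: with the line as a block, lines 34 and 37 gave a mean paired difference of 54.7 Mb.

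Compared with the S lists, the lists after the move held 2324.5 more domains and covered 1007 Mb more. Both lists after the move exceeded both S lists, with an exact permutation p of 0.333, two-sided, the smallest that 2 lists against 2 allow. Line 37, the only line with lists from all of these cultures, had 2937 domains after the move and 130 in its S culture. The difference in kind of the S domains given above applies here too.

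The Serum/LIF XS lists resembled the 2i/LIF lists in size and not the S lists, although the labels put XS and S samples in the same culturing condition. They held 3046 ± 1176 domains (SD, n = 3) over 1122 ± 552 Mb. Line 32 had the most domains of all lists, 4392, and the shortest outside the S lists, with a median of 79.3 kb, and line 31 covered 1755 Mb. Against the S lists the XS lists held 2968 more domains and 1117 Mb more, with an exact permutation p of 0.2, two-sided, again the smallest possible. Against 2i/LIF the difference was 69.3 domains (exact permutation p = 1) and -145 Mb (exact permutation p = 0.6), where 0.1 was the smallest p possible. Both directions turned without XS line 32, at -603.5 domains and 48.8 Mb; the number also turned without 2i/LIF line 34 (-119 domains) and the length without 2i/LIF line 35 (165 Mb). With S and XS lists pooled as Serum/LIF, 2i/LIF lists held 1118 more domains (exact permutation p = 0.393) and 592 Mb more (exact permutation p = 0.214), where 0.0357 was the smallest p possible. Single lists moved these values: the number was 1751 without XS line 32 (exact permutation p = 0.0571), 660 without S line 35 and 686 without S line 37, and the length was 282 Mb without 2i/LIF line 35. With the line as a block, lines 35 and 37 alone gave 3087.5 domains and 1478 Mb. This block leaves out every XS list, so it repeats the comparison with the S lists and does not bear on the pooled one. Over the 12 comparisons of size the lowest adjusted p (Benjamini-Hochberg, exact permutation tests) was 0.514.

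With S and XS lists as separate groups, the overlap index was higher within groups than between them. With S and XS lists counted as the 1 culture their labels give, it was not. The Jaccard index, the length shared by 2 lists over the length in either, averaged 0.477 within the 4 groups and 0.229 between them, with an exact permutation p of 0.0019, one-sided, over all 25200 relabellings of the 10 lists. By labelled culture the means were 0.273 and 0.274, a difference of -0.0012 (exact permutation p = 0.423, one-sided, over 2520 relabellings). Size alone holds the index of an S list with any other list near 0. The S lists cover 0.920 and 9.19 Mb, and the other lists 736 to 1886 Mb. Such pairs count as between groups in the first contrast, and those of S and XS lists as within in the second. The contrast by labelled culture therefore cannot show whether lists of 1 culture share regions. Without the S lists, where group and labelled culture coincide, the means were 0.532 and 0.404 (exact permutation p = 0.0429 over 560 relabellings); both settings were chosen after seeing the data. The highest index of all 45 pairs, 0.807, joined both lists of cells moved to Serum/LIF, although their line numbers differ. The next highest, 0.751, joined different cultures, namely the wide lists of 2i/LIF line 35 and XS line 31. Among the 3 pairs of 2i/LIF lists it ran from 0.421 to 0.646 and among the 3 pairs of XS lists from 0.411 to 0.463. The 6 pairs of a 2i/LIF list with a list after the move averaged 0.510, compared with 0.540 among the 2i/LIF lists and 0.432 among the XS lists. Of the 28 pairs outside the S lists, 24 shared more than circularly shifted lists did and 4 less. Each had an adjusted p under 0.05 by permutation. The lowest of the 24 had 1.04 to 1.08 times the overlap of shifted lists. They joined 2i/LIF line 35 or XS line 31 with a list after the move. Shifted domains also fall in the 8.36% of the span that no list covers. Overlap this little above that of shifted lists need not reflect sharing beyond such gaps. The 4 lower pairs all held XS line 32. Its overlap with 2i/LIF lines 34 and 37 and both lists after the move was 0.773 to 0.917 times that of shifted lists. All lists were called against a control that the sources used here do not identify, so part of the shared length may come from a shared control. A control used for 1 group only could also raise the overlap within that group. The 3 inputs of the series are from XS line 30, 2i/LIF line 35 and S line 35. XS lists come only from lines 30, 31 and 32, and the other lists from lines 34, 35 and 37. For the XS lists, group and line therefore cannot be told apart.

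**Figure D2:**
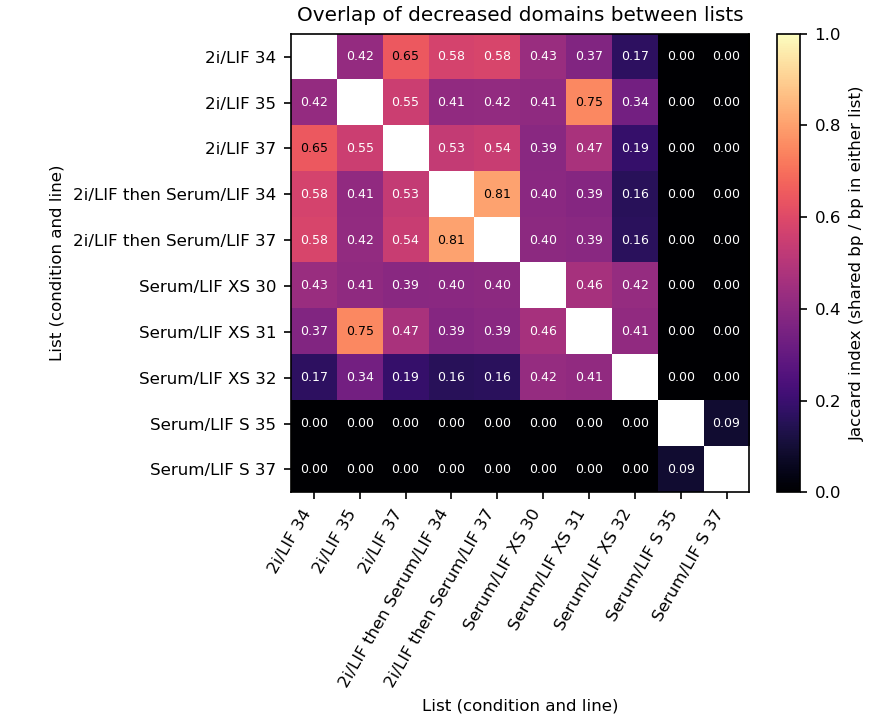
Jaccard index of each pair of the 10 lists, shown as colour and number, with condition and line on both axes; the diagonal is left blank. The brightest cell, at 0.807, is the pair of lists from lines 34 and 37 after the move to Serum/LIF, and every pair of an S list with another list lies near 0.

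A common set of regions was decreased in all 2i/LIF lists. Merging all lists gave 1683 regions, of which 932 were touched by all 3 2i/LIF lists and by no S list. The mean under 1000 circular shifts was 70.2, but shifting also joined the merged regions into a mean of 209, so the counts are not comparable and no p is given. By length, 741 Mb or 30.7% of the span lay in all 3 2i/LIF lists and in no S list, 2.46 times the mean of 302 Mb under shifts (permutation p = 0.001, the smallest possible); the condition on the S lists removed almost none of it. Of this length 82.9% was also in the list of line 34 after the move and 82.8% in that of line 37. XS lines 30 and 31 held 64.4% and 87.8% of it, and XS line 32 held 29.6%. Of the whole span, XS lines 30, 31 and 32 covered 36.3%, 72.8% and 30.5%, and the lists of lines 34 and 37 after the move 42.4% and 41.5%. The longest unbroken stretches, a ranking chosen after seeing the data, were on chromosome 2 from 168062701 to 173439500 (5.38 Mb, mm9), chromosome 4 from 151232901 to 154866400 (3.63 Mb), chromosome 15 from 77574901 to 80540200 (2.97 Mb), chromosome 7 from 50898901 to 53705600 (2.81 Mb) and chromosome 5 from 119211301 to 121589000 (2.38 Mb). Both lists after the move covered at least 97.0% of each of these 5. XS line 30 covered 88.1% to 100%, XS line 31 94.9% to 100% and XS line 32 56.6% to 91.4%. By contrast, the 2.23 Mb stretch on chromosome 8 from 120170701 to 122405400 was fully covered in 2i/LIF and XS line 31 and not covered at all in either list after the move. XS lines 30 and 32 covered 85.5% and 73.4% of it. The count of merged regions fell to 503 when each list had to cover at least 50% of a region. Genes were not assigned, because no annotation of mm9 was used here.

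Among the longest merged regions touched by all 2i/LIF lists and no S list, several were covered more by the XS lists and 2i/LIF line 35 than by 2i/LIF lines 34 and 37 or the lists after the move. The longest, on chromosome 16 from 65295101 to 94120000 (28.8 Mb, mm9), was covered over 61.5%, 97.9% and 69.4% by XS lines 30, 31 and 32 and over 86.6% by 2i/LIF line 35, compared with 14.9% and 28.3% by 2i/LIF lines 34 and 37 and 25.2% and 26.3% by the lists after the move. On chromosome 15 from 12103001 to 26626600 (14.5 Mb) the XS lists covered 41.2%, 98.6% and 66.8%, 2i/LIF line 35 94.7%, 2i/LIF lines 34 and 37 7.99% and 32.9%, and the lists after the move at most 13.2%. The region on chromosome 14 from 87492601 to 99515000 (12.0 Mb) was covered over 59.8%, 94.4% and 83.6% by the XS lists, 94.9% by 2i/LIF line 35, 0.595% by line 34, 12.5% by line 37, and 2.53% and 3.29% by the lists after the move. Strong coverage in every 2i/LIF list was seen on chromosome 2 from 160681301 to 174790200 (14.1 Mb), where lines 34, 35 and 37 covered 88.6%, 96.5% and 92.6% and the lists after the move 96.0% and 93.6%. XS lines 30, 31 and 32 covered 88.0%, 93.2% and 61.5% of it. A second such region lay on chromosome 5 from 113986601 to 125097700 (11.1 Mb), with 87.8%, 90.4% and 91.3% in 2i/LIF and 99.7% and 97.6% after the move. The XS lists covered 86.5%, 88.1% and 53.4% of this region. On chromosome 8 from 114036001 to 125437000 (11.4 Mb) the 2i/LIF lists covered 70.7%, 90.9% and 55.4%, the XS lists 66.5%, 93.4% and 63.9%, and the lists after the move 3.85% and 2.82%.

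Most of the length decreased in 2i/LIF was still decreased in the same line after the move. The share retained was 81.4% in line 34 and 67.8% in line 37, with a mean of 74.6% against 44.1% under circular shifts (permutation p = 0.001, the smallest possible). Without chromosomes 6, 8 and 13, a setting chosen after seeing the data, the mean was 82.2%. Overlap was similar with the 2i/LIF then Serum/LIF list of the other line: the 2i/LIF list of line 34 had an index of 0.577 with the 2i/LIF then Serum/LIF list of line 34 and 0.583 with that of line 37, and the 2i/LIF list of line 37 had 0.543 with its own and 0.531 with the other. Nor was coverage of the 2i/LIF lists particular to lists after the move. XS line 31 covered 84.4% and 83.9% of the 2i/LIF lists of lines 34 and 37, against 72.6% for both under shifts. XS line 30 covered 61.8% and 50.9%, against 36.9% for both. XS line 32 covered 27.6% and 26.9%, against 30.1% and 29.9%. A total of 96.4 Mb was in all 2i/LIF lists and in neither list after the move, and 66.3% of it was on chromosomes 6 and 8, which make up 11.4% of the span.

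Domains were spread unevenly over chromosomes. Chromosome 11 had the highest coverage in 2i/LIF lines 34 and 37, in both lists after the move and in XS line 30, with 52.6%, 62.0%, 65.9%, 62.4% and 46.7%. Chromosomes 6 and 8 had the lowest coverage after the move in both lines: line 34 had 4.37% of chromosome 6 and 1.16% of chromosome 8 covered, and line 37 had 0.0355% and 0.280%, while their other 17 chromosomes lay between 35.7% and 65.9%. In line 37 both were already low in 2i/LIF, at 27.4% and 30.8% against a mean of 47.7% for the other 17, whereas in line 34 they were at 31.5% and 35.6% against 35.3%. Chromosome 19 was also less covered after the move in line 34, at 36.5% against 44.1% in 2i/LIF, while the mean of the 17 rose by 12.1 percentage points. In line 37 a stretch of 112.9 Mb on chromosome 6 (3000401 to 115893700, mm9) and one of 110.6 Mb on chromosome 8 (12967501 to 123533800) held no domain. Chromosomes 6 and 8 together were covered over 1.51% ± 1.92 (SD, n = 2) after the move and 46.2% ± 26.1 (SD, n = 3) in 2i/LIF, a difference of -44.7 percentage points (exact permutation p = 0.2, two-sided, the smallest possible), or -29.7 without 2i/LIF line 35. In XS line 32 chromosome 13 was covered over 0.0821%, with only 3 domains, and the next lowest chromosome over 23.8%; chromosome 13 was also the lowest in XS lines 30 and 31, at 21.6% and 61.9%. A test of single chromosomes between 2 lists and 3 could not pass, since its smallest exact permutation p is 0.2. The lists of lines 34 and 37 after the move had the highest overlap index of all pairs, 0.807. Because 1 culture under both numbers is not excluded, their low chromosomes 6 and 8 may be 1 event.

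**Figure D3:**
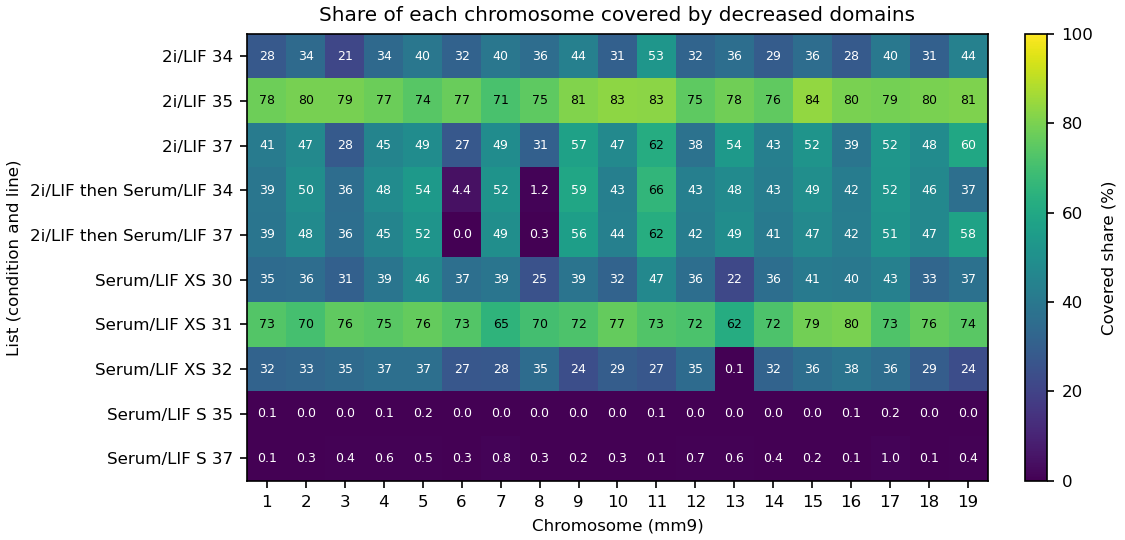
Share of each of the 19 autosomes (mm9, horizontal axis) covered by decreased domains in each list (vertical axis), in percent, as colour and number. Chromosomes 6 and 8 have the lowest coverage in both lists after the move to Serum/LIF, at 4.37% and 1.16% in line 34 and 0.0355% and 0.280% in line 37, and chromosome 13 is nearly empty in XS line 32.

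**Figure D4:**
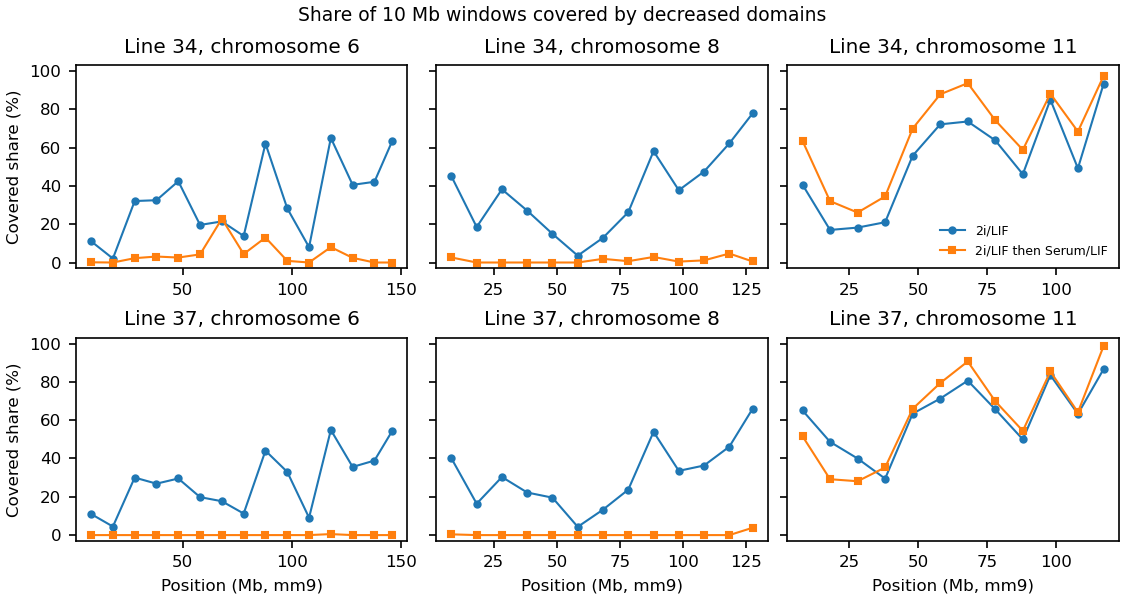
Covered share in percent of consecutive 10 Mb windows along chromosomes 6, 8 and 11 (position in Mb, mm9) for line 34 (top) and line 37 (bottom), in 2i/LIF (circles) and after the move to Serum/LIF (squares). On chromosomes 6 and 8, 55 of the 56 windows of both lines are lower after the move, whereas chromosome 11 keeps a covered share of 65.9% in line 34 and 62.4% in line 37.

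The S lists held a small set of shared places. Of the 26 S domains of line 35, 23 were touched by a domain of line 37, 12 had identical ends in both, and 91.9% of their length was covered, 186 times the value under circular shifts (permutation p = 0.001, the smallest possible). The longest shared places, ranked after seeing the data, were on chromosome 5 from 26332801 to 26423800 (91 kb, mm9), chromosome 17 from 3000401 to 3086200 (85.8 kb) and chromosome 4 from 145037101 to 145120300 (83.2 kb). Some of the 10 longest lay near the start of a chromosome's span, on chromosomes 11, 16 and 17. Another, on chromosome 1 from 87471801 to 87522500, began where a stretch in no list ended. The shifts move domains to any position alike, so the ratio of 186 does not account for such places. In line 35, 4 of the 26 domains began within 0.5 Mb of the start of the covered span of a chromosome, and in line 37, 11 of 130. These starts are 0.5 Mb on each of 19 autosomes in a span of 2412.2 Mb, so both counts exceed an even spread. On chromosome 16 the span itself began with a shared place, at 3231801. The longest merged regions touched by both S lists were on chromosome 2 from 24768901 to 34045700 (9.28 Mb) and chromosome 15 from 73197801 to 81169400 (7.97 Mb), but the S lists covered at most 0.571% of either.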

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

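Covered length moved in opposite directions in the 2 lines that were followed from 2i/LIF to Serum/LIF, a feature of the data picked out after the values were seen. In line 34 the list after the move covered 188 Mb more than the 2i/LIF list. In line 37 the difference was -78.9 Mb. Each line has 1 list per culture, and the difference between the lines was not tested. Over the 17 chromosomes other than 6 and 8 the mean change was 12.1 percentage points in line 34 and -0.187 in line 37.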

How the results depend on the processing

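Of 178 alternative values, 166 kept their direction and their side of the threshold, or stayed close to the reported count. For the length difference between lists after the move and 2i/LIF, leaving out each replicate gave -471 to 54.7 Mb, and the line as a replicate block gave 54.7 Mb (exact permutation p = 1, 2 paired lines); both positive values omit 2i/LIF line 35, the widest list, by construction. Paired values changed no other direction or call. For the number of domains in that comparison, leaving out each replicate gave -1109 to -40. For XS against 2i/LIF, leaving out each replicate gave -603.5 to 486 domains and -461 to 165 Mb, and log10 of the number of domains gave -0.0081; the cause was not tested. The count of regions touched by all 2i/LIF lists and no S list was 932, and it was 528 with the higher-scoring 50% of each list, 503 when at least 50% of a region had to be covered, and 0 when every list was reduced to 26 domains, which leaves too few domains to meet. The excess of the overlap index within groups was 0.247 with S and XS lists as separate groups and rested on that division. With S and XS lists as 1 labelled culture it was -0.0012 (exact permutation p = 0.423). As a bin correlation, also with 1 labelled culture, it was 0.106 (exact permutation p = 0.106). The pairs of S and XS lists then count as within, and the small size of the S lists alone holds their index near 0. The joint culture, the omission of chromosomes 6, 8 and 13 or of the S lists, and the bin correlation were chosen after seeing the data; with S and XS lists apart, the excess without those chromosomes was 0.244, and the 10 versions leaving out a replicate gave 0.222 to 0.286. With every list reduced to 26 domains, the excess was 0.0113 (exact permutation p = 0.0229) and retention was 5.50% against 0.348% under shifts, compared with 74.6% for the full lists. For 2i/LIF against all Serum/LIF lists, leaving out each replicate gave 660 to 1751 domains and 282 to 861 Mb. Comparisons of list sizes that could not reach a p of 0.05 say nothing of stability. The alternative with autosomes only changed nothing, since all domains are autosomal; an overlap of at least 50% has no meaning for the index of lists, and the gene list alternatives were not run. Depth is unknown, so its limit on these lists was not tested.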

Other observations

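All tests of explanations in this part were chosen after the result was seen, except the test of the pair of lists after the move without chromosomes 6 and 8.

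Some parts of the autosomes were in no list. These made up 202 Mb, or 8.36% of the span, and the longest stretches were on chromosome 7 from 39295101 to 46413900 (7.12 Mb, mm9), chromosome 14 from 4518801 to 7736300 (3.22 Mb) and chromosome 7 from 21574801 to 23936900 (2.36 Mb). At the other end, 185 Mb, or 7.67% of the span, were in all 8 lists outside the S lists. A further 107 Mb were in both lists after the move and in no 2i/LIF list, and 70.8 Mb were in all 2i/LIF lists and in no XS list. The lists of 2i/LIF line 35 and XS line 31 stayed wide when each domain was weighted by its score, at 1.57 and 1.90 times the highest other list of their group.

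Chromosomes 6 and 8 lost most of their covered length after the move to Serum/LIF in the lists of both line numbers. They fell to 4.37% and 1.16% in line 34 and to 0.0355% and 0.280% in line 37. In line 37 they were already the lowest and the third lowest in 2i/LIF. Cells of 1 culture under both numbers are not excluded, as the next paragraph sets out, so this may be 1 event and not a recurrence. Sequence that cannot be called is argued against, since every 2i/LIF and XS list covered at least 25.07% of both chromosomes, and so is a change in calling across the list, since the lower of the mean changes of the other 17 chromosomes was -0.19 percentage points. Extra copies of these chromosomes, which would raise reads along their whole length, could also remove decreased domains; trisomy of chromosome 8 is a known abnormality of cultured mouse embryonic stem cells. That 98.2% of their 10 Mb windows were less covered than in 2i/LIF decides nothing, since chromosomes with so little coverage give this whatever the cause. Extra copies therefore stay a hypothesis that cannot be told apart from a change of H2A.X along both chromosomes, because the lists hold no input signal. A difference in the control, which is not identified, cannot be told apart from these either. The 3 inputs of the series are from XS line 30, 2i/LIF line 35 and S line 35, and none is from a culture after the move. A similar gap without the move was seen in XS line 32, where chromosome 13 was covered over 0.0821%.

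The lists after the move resembled each other across lines more than the 2i/LIF list of their own line. The shared gap as the reason is argued against, since without chromosomes 6 and 8 their Jaccard index was 0.813, compared with 0.620 and 0.577 for each with its own 2i/LIF list. Similar size as the reason for the gap to the own-line pairs is argued against too, since relative to the largest index that the sizes allow the pair reached 0.825 and the own-line pairs 0.707 and 0.586. On this scale the pair did not stand out, as the 9 other pairs of lists with 2i/LIF history ran from 0.561 to 0.965. That scale is high where a list lies inside a wide one. The value of 0.965 was for 2i/LIF lines 35 and 37, whose shared length was 1.25 times that under shifts. As a correlation over bins, the pair had 0.817 and the 9 other pairs 0.0981 to 0.662. Cells of 1 culture under both numbers cannot be told apart from a shared effect of the culture change, because the largest difference between the lists, 21.2 percentage points on chromosome 19, could also arise between libraries of 1 culture. An effect of culture history, which the groups name, stays open and was not tested apart from these.

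The S lists were small and overlapped the domains of the other lists less than chance. The largest share of an S list inside another list was 30.6%, for S line 35 in the list of 2i/LIF line 35. The same kind of domain called in smaller number is argued against, since it would place S domains within the others, and the highest ratio of observed to expected overlap over the 16 pairs was 0.485. A candidate explanation is that the S lists hold the other direction of difference from the control: column 5 was above 0 in 100% of S domains and in at most 16.8% of the domains of any other list. That sign was known before it was used here and the meaning of the column is not given in the sources used here, so this explanation stays open, and lists of increased domains were not analysed here. Serum culture alone does not go with small lists, since the XS lists, labelled with the same culture, held 3046 ± 1176 domains (SD, n = 3).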
